A study of Mus musculus with 2 samples.

How the data were processed

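Small RNA from ischemic mouse hindlimb muscle was profiled in 2 libraries, 1 hypercholesterolemic (HC) and 1 normocholesterolemic (NC), both taken 1 day after surgery. Per the labels' protocols, RNA was extracted with Trizol and the mirVana kit and made into libraries with the Illumina TruSeq small RNA preparation. Groups were taken from the phenotype labels. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.10 and HTSeq 0.5.4 and the mouse build mm10. The steps in which these tools were used, the adapter trimming, the treatment of reads with several alignments and the miRNA annotation are not given in the sources used here.

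The deposited files give whole-number read counts per miRNA precursor, the hairpin from which the mature miRNA is cut, with coordinates, for 1187 precursors, and 5 summary rows of the kind HTSeq writes. A count for a precursor sums reads of both its arms, so the mature 5p and 3p products were not separated. The deposited summary rows list 39620970 counts outside all precursors in HC (55.9% of all counts) and 34643677 in NC (44.1%), and 0 counts as ambiguous or not unique in either library. These rows stayed out of library sizes and comparisons. Reads were listed in more than 1 precursor: of 22 overlapping precursor pairs with counts, 15 differed by under 1% in both libraries, among them miR-486a and miR-486b and the miR-451a and miR-451b hairpins, which lie on opposite strands with equal counts. Precursors that overlap or are copies of each other are therefore described together, and their separate levels are uncertain.

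A further column, which the deposited headers call RPM, was treated as a signal scaled by the authors. Within a library it was a constant multiple of the count, with a denominator of 27222821 in HC and 32252170 in NC. Its values summed to 1146030 in HC and 1359550 in NC, so it is not a plain share of these counts, and what the denominator counts is not given in the sources used here. It served only for an alternative scaling.

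All 1187 precursors had the coordinates of a miRNA gene in GENCODE mouse release M21 (GRCm38, the assembly of mm10), which gave host genes, exons or introns, neighbouring noncoding genes and hairpin sequences. Counts were scaled by library sizes from the trimmed mean of M-values (TMM), which assumes that most features do not differ, with edgeR 4.0.16 in R 4.3.3 and without any edgeR test. CPM stands for counts relative to the scaled library size, multiplied by 1e6. At a mean of at least 10 CPM, 222 precursors were compared. The log2 fold is the ratio of HC to NC counts per scaled library size, with no pseudocount. Its 95% interval is the exact conditional binomial (Clopper-Pearson) interval, and shares of counts have exact Clopper-Pearson intervals. Sequencing reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. A count of 0 was given the limit of 3 counts per library, and no fold was formed where both libraries were at or below it. With 1 library per group, no p-value was computed.

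The following were fixed before the data were examined: the size rule, the miRNA lists, the naming rule and the alternatives. A precursor counted as higher or lower when its mean over both libraries was at least 10 CPM, its fold at least 2 and its interval excluded equality. Named miRNAs were the 10 with the most counts, up to 12 per direction by the size rule (preferring a mean of at least 50 CPM), and in each list the members past the size rule or otherwise its 4 most abundant. Copies and overlapping precursors were named together, and miRNAs named outside this rule are marked where they appear. In all, 20 lists were fixed (muscle; myoblast differentiation and regeneration; erythrocyte; myeloid cell; lymphocyte; inflammation; endothelial cell; smooth muscle cell; fibroblast and matrix; hypoxia; the miR-17-92 clusters; angiogenesis; the Dlk1-Dio3 cluster; lipid and cholesterol metabolism; liver; neuron and Schwann cell; adipocyte; epithelium and skin; let-7; miR-30). The members of several lists overlap. The liver list holds miR-122 alone, which lay below 10 CPM. For the 17 lists with at least 3 compared precursors, the median was placed among the medians of 10000 random lists of the same size, matched by 10 bins of mean CPM. This percentile describes these libraries and is not a test of the conditions.

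The procedure was tested on simulated Poisson counts for the HC versus NC comparison, with 200 of the 1187 precursors changed. Of those at a mean of at least 10 CPM, all 15 raised 4-fold and all 10 lowered 4-fold were recovered, as were 8 of 18 raised exactly 2-fold and 8 of 20 lowered exactly 2-fold, which lie on the limit. None of 162 unchanged precursors was called. The nominal 95% interval held the simulated fold for 92% of these precursors; the intervals take the scaled library sizes as known. Of 100 random lists, 4 fell outside the central 95%. The simulated counts held no spread between animals and no reads shared between precursors, so they show nothing about false calls from either. Simulated precursors did not share folds as clusters or copies do, so the percentiles of fixed lists that hold these were not checked. The alternatives were plain totals, DESeq2 1.42.0 size factors, upper-quartile scaling, totals without the 10 most abundant precursors, copies summed, means of at least 1 or 50 CPM, no filter, and an interval wholly beyond 2-fold. The authors' denominators and 1 precursor per set of copies were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.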

Results

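Small RNA was sequenced from mouse hindlimb muscle taken 1 day after ischemia had been induced by surgical removal of the femoral artery. The 2 libraries were a hypercholesterolemic one (HC), from Apoe-/- mice on a high-fat diet, and a normocholesterolemic control (NC), from C57Bl/6 mice. Apoe encodes apolipoprotein E, a ligand for the hepatic clearance of lipoprotein remnants, and its loss raises plasma cholesterol. The comparison asks which miRNAs differ in ischemic muscle between the hypercholesterolemic and the normocholesterolemic state. Each group held 1 library, and the labels do not say how many mice went into it. The spread between animals could therefore not be estimated, no test was run, and every interval given here is a nominal 95% interval of counting error only. Genotype differed between the libraries together with the diet, as far as the series' design text states it, and counts of miRNA precursors do not measure Apoe itself, so the genotype label was not checked against the data.

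The HC library held 31198050 counts over the listed miRNA precursors (hairpins) and the NC library 43848576. Counts above 0 were listed for 663 precursors in HC and 691 in NC, and 599 precursors had counts in both. The 64 precursors seen in HC alone had at most 5 counts, and the 92 seen in NC alone had at most 6. A count of 0 allows up to 0.0918 CPM (TMM-scaled counts) in HC and up to 0.0717 CPM in NC. The counting interval of an abundant miRNA is narrow at this depth, and it describes these libraries only.

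The same miRNAs dominated both libraries. With 1 precursor kept for each set of copies or overlapping precursors, the 10 most abundant sets took 79.8% of the counts in HC and 80.3% in NC. The muscle-enriched miR-486 (chromosome 8, 23142555 to 23142682 in mm10, in an intron of Ank1) was the most abundant, with 21.2% of counts in HC (exact interval 21.1 to 21.2%) and 26.2% in NC (26.1 to 26.2%). miR-22 (chromosome 11, 75463716 to 75463810, in an exon of its host transcript Mir22hg) took 13.1% in HC and 10.2% in NC. miR-10b (chromosome 2, 74726070 to 74726137, in introns of Hoxd3 and Hoxd4) took 12.4% and 11.8%. The smooth muscle-enriched miR-143 (chromosome 18, 61649196 to 61649258) took 10.3% and 10.7%, and the muscle-specific miR-133a took 9.74% and 9.13%. miR-30a, miR-26a, miR-10a, miR-27b and miR-181a completed the 10, with 1.89% to 4.21% of counts each in HC.

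The miRNA profiles of hypercholesterolemic and normocholesterolemic ischemic muscle were close in level. Of the precursors with a mean of at least 10 CPM, 92.8% lay within 1.5-fold between the libraries, 6 were at least 1.5-fold higher in HC and 10 at least 1.5-fold lower (14 and 5 with plain totals). The median log2 fold of HC over NC was 0.00, a value that TMM scaling largely sets and that does not measure closeness. The central 90% of precursors lay between -0.47 and 0.47. Across precursors, which are not independent replicates, the log2 CPM values correlated with r = 0.994 and rho = 0.991. The counting interval excluded equality for 88 precursors with a higher and 97 with a lower value in HC, a split that depended on the scaling. It was 135 higher and 47 lower with the plain totals, which shift every log2 fold by 0.13, and 55 higher and 131 lower with the authors' own denominators, which shift it by -0.11. Values within that range of 0 have no firm direction and are given without one, and counts of list members above or below 0 refer to TMM scaling and to intervals that exclude 0.

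At a mean of at least 10 CPM, 5 precursors differed by at least 2-fold with an interval that excluded equality, 3 higher and 2 lower in HC. miR-6236 (chromosome 9, 110281287 to 110281409, outside any other annotated gene) was 4.19-fold higher in HC (3.99 to 4.40), at 210.7 CPM against 50.3 in NC. miR-6240 (chromosome 5, 114851948 to 114852064, also outside other genes) was 3.19-fold higher (2.97 to 3.43), at 81.1 against 25.4 CPM. miR-3535 (chromosome 1, 86351981 to 86352127) was 2.46-fold higher (2.24 to 2.71), at 39.0 against 15.8 CPM. Its annotated hairpin spans the snoRNA gene Gm24148 within Ncl, the gene of nucleolin, so the counts do not separate reads of that snoRNA from reads of the miRNA. miR-5103 (chromosome 1, 34433121 to 34433199, in an exon of the long noncoding RNA Gm37233) was 2.05-fold lower in HC, at 343.5 CPM against 703.7, and stayed under the 2-fold limit with the plain totals. miR-92b (chromosome 3, 89227116 to 89227198, outside other genes) was 2.49-fold lower, at 8.96 against 22.3 CPM. With plain totals the split was 3 higher and 1 lower, at a mean of at least 1 CPM it was 8 higher and 5 lower, and with totals that leave out the 10 most abundant precursors it was 6 higher and 4 lower. None of the 5 belongs to any of the 20 miRNA lists fixed for this tissue. The share of counts that fell outside all precursors was also higher in HC, 55.9% against 44.1%.

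**Figure D1:**
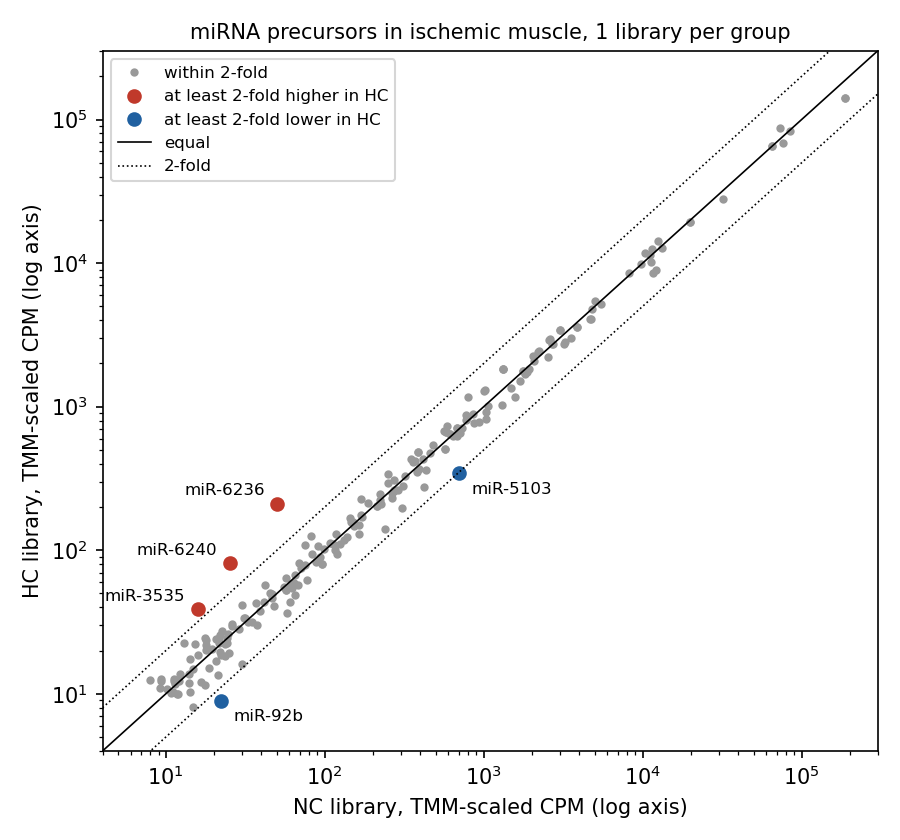
TMM-scaled CPM of the miRNA precursors with a mean of at least 10 CPM, NC library on the x axis and HC library on the y axis, both logarithmic. Each point is 1 precursor, and 3 lie at least 2-fold higher and 2 at least 2-fold lower in HC, while the others lie between the dotted 2-fold lines.

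Muscle-enriched miRNAs did not share a direction. Among the 11 compared precursors of the muscle list, 5 were higher in HC and 6 lower by their counting intervals, and none reached 2-fold. This tally counts the inseparable precursors of miR-1, miR-486 and miR-133a separately. The lower ones include miR-133a and miR-206, which have no firm direction. miR-1, the most muscle-specific miRNA, was higher in HC, with a log2 fold of 0.47 for each of the precursors miR-1a-1, miR-1a-2 and miR-1b, whose counts were nearly equal and which cannot be separated. miR-486, also abundant in erythrocytes, was lower at -0.40, and miR-133b was lower at -0.20. miR-133a lay at -0.01, although miR-133a-1 and miR-1a-2 lie in an intron of the same host gene, Mir133a-1hg. In level, miR-1a-1 had 1826 CPM in HC and 1320 in NC, far below the 65127 and 65383 of miR-133a-1. Why miR-1 and miR-133a differed in level and in fold was not tested. Outside the rule for named miRNAs and chosen after their values were seen, miR-208b (0.55, in an intron of the slow myosin gene Myh7) and miR-499 (0.63, in an intron of Myh7b) were higher in HC, while miR-206, induced in regenerating fibres, lay at -0.09. The list median of -0.01 stood at percentile 62.9 of 10000 random lists matched on abundance. Its mean was 0.13.

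miRNAs tied to myoblast differentiation and regeneration lay close to equality. Their 21 compared precursors had a median log2 fold of 0.04 (percentile 75.4), with 10 above and 9 below 0. miR-181a was 0.19 and 0.15 for its precursors, while miR-26a (-0.02), miR-27b (-0.05) and miR-378a (-0.13) had no firm direction. The 21 compared precursors of the imprinted Dlk1-Dio3 cluster on chromosome 12, whose miRNAs are active in growing muscle, had a median of 0.10 (percentile 89.0) and spread widely. The median was -0.01 with the authors' denominators, and the list lay outside the central 95% at a mean of at least 1 CPM and with no filter (0.11, percentile 99.2). miR-434 was 0.56, miR-136 and the overlapping miR-3071 were 0.21, miR-127 was 0.05 and miR-411 was -0.17. The extremes, chosen after their values were seen, were miR-376b at 0.80 and miR-381 at -0.64.

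At a mean of at least 10 CPM with TMM scaling, epithelial miRNAs were the only list that stood apart from matched random lists, and they were lower in HC. All 5 compared members lay below 0: miR-205, a miRNA of stratified epithelium, at -0.66 (-0.82 to -0.49), miR-200b at -0.62 (-0.81 to -0.44), miR-141 at -0.46 (-0.55 to -0.36), miR-203, abundant in keratinocytes, at -0.20 (-0.29 to -0.11), and miR-429, named outside the rule after its value was seen, at -0.88 (-1.09 to -0.67). With plain totals all 5 values stayed below 0, but the interval of miR-203 reached 0. The median of -0.62 was at percentile 0.085, where the central 95% of random lists ran from -0.35 to 0.26. All 5 were low in muscle, between 8.14 and 54.3 CPM in HC and between 14.9 and 62.4 CPM in NC. Of 17 lists set against random lists, chance alone would place 0.85 outside the central 95% if list members were unrelated. However, miR-200b and miR-429 come from 1 genomic cluster. At a mean of at least 50 CPM only 2 members remained (median -0.33), too few for a percentile.

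Blood and immune cell miRNAs went in different directions. The erythroid miR-144 was higher in HC at 0.62 (0.55 to 0.68) and miR-451 at 0.32 (0.29 to 0.36), a list median of 0.32 at percentile 97.1, on the upper edge of the central 95%. It lay outside in 3 alternatives, at percentiles up to 98.3. Of its 3 precursors, miR-451a and miR-451b hold the same counts, and with 1 precursor per set of copies the median was 0.48, with too few members for a percentile. All 3 also come from 1 genomic cluster on chromosome 11, so random lists of unrelated precursors are a loose measure for this list. Among myeloid miRNAs, the neutrophil-enriched miR-223 was higher at 0.44 (0.40 to 0.48), while the pan-leukocyte miR-142, in 2 overlapping precursors with nearly the same counts, lay at 0.01, which is also the list median (percentile 61.0). The shared reads of miR-142 set that median, which was 0.22 with 1 precursor per set of copies and 0.21 (percentile 96.2) with no filter. The lymphocyte-enriched miR-150 was lower in HC at -0.75 (-0.80 to -0.70), at 141.6 against 237.6 CPM. With miR-181d at -0.23 and miR-155 at -0.05, the lymphocyte list had a median of -0.23 (percentile 6.06), or -0.49 over the members at a mean of at least 50 CPM. Of the inflammatory miRNAs induced through NF-kB, miR-146b was lower at -0.41 and miR-146a was 0.14, while miR-21a was -0.08 and miR-221 was -0.03. This list's median was -0.05 (percentile 34.2), with 2 of 7 members above and 3 below 0.

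Angiogenic and vascular miRNAs showed no common shift. The 27 compared precursors of the angiogenesis list had a median of -0.01 (percentile 40.3), 10 above and 11 below 0. miR-126a, the main endothelial miRNA, hosted in Egfl7, was 0.03, the overlapping miR-126b was 0.01, and the hypoxia-induced miR-210 was 0.05 (-0.10 to 0.19), a difference not detectable at this depth. miR-10a was 0.20 and miR-10b -0.02, which left the endothelial list at 0.02 (percentile 79.4). In the miR-17-92 family and its paralogs, 7 of 10 precursors lay below 0 and 1 above, with miR-92a-1 at -0.25, miR-92a-2 at -0.20, miR-19b at -0.26, miR-93 at -0.10 and miR-25 at -0.08. That list's median was -0.15 (percentile 4.75), and it depended on the setting. It was -0.07 (percentile 27.3) with 1 precursor per set of copies, -0.06 with copies summed, -0.02 with plain totals, -0.26 with the authors' denominators and -0.20 (percentile 2.59) with no filter. The smooth muscle miRNAs miR-143 and miR-145a were -0.14 and -0.06, a list median of -0.10.

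miRNAs known to act on lipid and cholesterol metabolism did not shift as a group. Their 18 compared precursors had a median of -0.04 (percentile 49.4), with 7 above and 11 below 0. miR-148a, which targets the LDL receptor, was -0.19, miR-30c was -0.11, and miR-26a and miR-27b lay near 0 as above. The list ranged from -0.68 for miR-183, chosen after its value was seen, to 0.62 for miR-144. The liver-specific miR-122 had 7 counts in HC and 9 in NC, so no difference in it was detectable at this depth.

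Of the remaining lists, the fibroblast and matrix list had a median of 0.13 (percentile 91.9), with miR-199a and miR-199b at 0.13, miR-29a at 0.06 and miR-21a as given above. The adipocyte list had a median of 0.13 (percentile 93.2), with miR-196a at 0.16 and 0.20, miR-196b at 0.21, miR-365 at 0.08 and 0.09 and miR-193b at -0.11. The neuron and Schwann cell list stood at 0.14 (percentile 85.2), with miR-128 at 0.19, miR-138 at 0.08 and miR-338, whose counts equal those of the overlapping miR-3065, at -0.06. Its direction did not hold: the median was -0.02 with the authors' denominators, -0.06 at a mean of at least 1 CPM and -0.27 (percentile 3.41) with no filter. In the let-7 family, let-7f was lower in HC at -0.45 and -0.44 and let-7i at -0.23, whereas let-7c was higher at 0.18 and 0.19 and let-7a lay at 0.02, which gave a median of -0.06 (percentile 25.9). That median was -0.11 (percentile 7.05) with copies summed and -0.12 with 1 precursor per set of copies. The miR-30 family had a median of -0.11 (percentile 13.7), with miR-30a at -0.19, miR-30e and miR-30f, which hold the same counts, at -0.10 and miR-30d at -0.01.

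**Figure D2:**
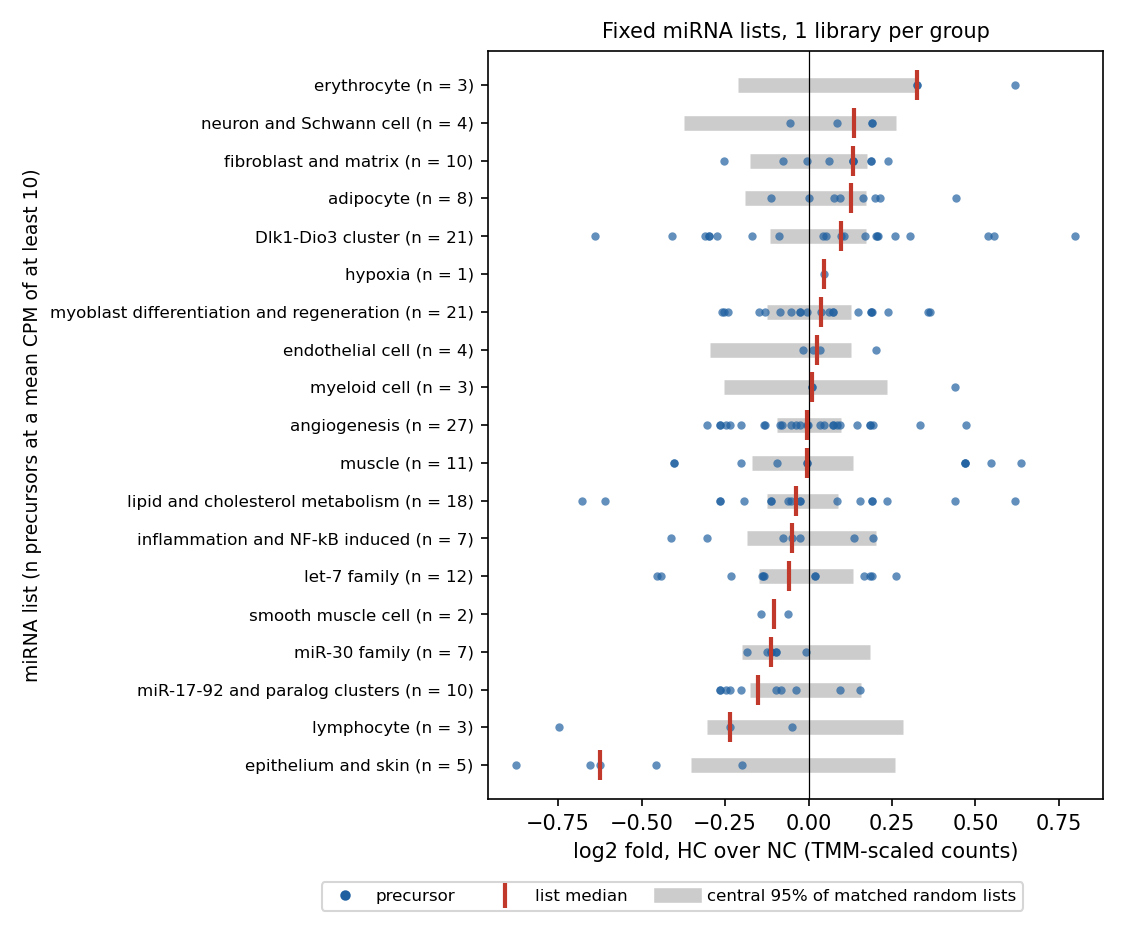
Log2 fold of HC over NC (x axis, TMM-scaled counts) for each compared precursor of 19 fixed miRNA lists (y axis, blue points), with each list's median (red bar) and, for lists of at least 3 precursors, the central 95% of matched random lists (grey band). The epithelium and skin list is the only one whose median, -0.62, lies outside its band.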

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

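The tests on counts outside the precursors, on the members of the epithelium list, on miR-150 and on miR-142 were chosen after seeing the values. Those on snoRNA-like genes and on hairpin GC were written before their own results, but for patterns already seen in the values.

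Counts outside all miRNA precursors made up 55.9% of all listed counts in HC and 44.1% in NC. They took no part in the comparisons and are listed because the share in HC exceeds that in the control. Per scaled library size they were 1.46-fold higher in HC, a log2 ratio of 0.55. These counts may not be distinct reads. They exceed the authors' RPM denominator in both libraries, with 39620970 against 27222821 in HC and 34643677 against 32252170 in NC. The percentages are therefore shares of listed counts, which need not equal shares of reads, and the same limit holds for the ratio.

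The 3 precursors at least 2-fold higher in HC at a mean of at least 10 CPM were miR-6236, miR-6240 and miR-3535. They raise the question whether they follow the counts that lie outside the precursors. An even rise of all counts outside would cap the log2 folds of these 3 at 0.55, and the lowest of their lower counting bounds was 1.16. They were chosen for a fold of at least 2, which already lies above that cap, so the comparison is no separate check. It shows only that the counts of these 3 were higher in HC by more than the counts outside as a whole. A rise of fragments of particular noncoding RNAs stays open. The 10 other precursors at a mean of at least 1 CPM that overlap a snoRNA, scaRNA or similar gene had a median log2 fold of 0.21. It stood at percentile 96.5 of matched random lists (central 95% -0.24 to 0.23), which decides neither way for miR-3535. These precursors were split. Intervals lay below 0 for miR-1839 (-0.21), miR-1843a (-0.16), miR-1843b (-0.33) and miR-664 (-0.15). They lay above 0 for miR-3068 (0.28), miR-6516 (0.48) and miR-5121 (2.33), and held 0 for miR-677 and both copies of miR-3084. miR-6236 and miR-6240 overlap no such annotated gene, ribosomal RNA sequence was not searched, and a difference due to hypercholesterolemia was not tested.

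For the lower epithelial miRNAs in HC, a smaller amount of skin or other epithelium in the HC tissue sample is a candidate explanation that the values do not decide. The 5 compared members are the pattern itself, and miR-200a (-0.36) and miR-200c (-0.85), the others at a mean of at least 1 CPM, lie within 10 kb of compared members, which leaves 0 members for a separate check. The most abundant, miR-203, was at 54.3 CPM in HC and 62.4 in NC (-0.20), none of the 7 belongs to another list, and miR-182 (-0.61) and miR-183 (-0.68), also found in epithelium, were lower too but were picked after their values were seen and stand on no epithelial list, so they decide nothing. Hairpin GC content correlated weakly with the fold across precursors (r = -0.18), with a fitted slope of -0.079 per 10 percentage points. The 5 compared hairpins held 48.7 to 51.4% GC, so a linear correction could hardly move them. The list's median stayed at -0.62 (percentile 0.24 of matched random lists). This argues only against a linear trend with hairpin GC. The GC of the mature arms and other sequence biases were not tested. With 1 library per group, tissue sampling and an effect of genotype or diet on epithelial miRNAs stay open.

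miR-451, miR-144 and miR-223 were higher in HC while miR-150 was lower. More residual whole blood in the HC muscle would not lower miR-150, whose upper counting bound was -0.70. That bound is part of the pattern and no separate check. More residual whole blood leaves this part of the pattern unexplained. For miR-451, miR-144 and miR-223 it stays open: miR-142, held by blood leukocytes and by those in the tissue alike, was at 0.011 with an interval that holds 0 (-0.0051 to 0.026). miR-486, abundant in erythrocytes but also muscle-enriched, went the other way at -0.40, and its counts do not separate these sources. More erythrocytes or neutrophils alone, fewer lymphocytes, and an effect of the hypercholesterolemic state stay open and untested.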

How the results depend on the processing

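The alternatives with the authors' denominators and with 1 precursor per set of copies were chosen after seeing the data. The direction of every 2-fold difference held under each scaling and treatment of copies. This was fixed in advance, since the largest shift of these log2 folds was 0.13 in size. The same 3 miRNAs (miR-6236, miR-6240, miR-3535) were counted as higher under plain totals, DESeq2 factors, upper-quartile scaling, the authors' denominators and summed copies. They were also counted with an interval wholly beyond 2-fold. The number higher in HC, 3, became 6 with totals that leave out the 10 most abundant precursors, 5 with 1 precursor per set of copies (miR-2137 and miR-5121 added), 8 at a mean of at least 1 CPM, 20 with no filter and 2 at a mean of at least 50 CPM (miR-3535 lost). The number lower, 2, became 1 with plain totals (miR-92b), 1 at a mean of at least 50 CPM (miR-5103), 4 without the 10 most abundant (miR-483 and miR-8114 added), 5 at a mean of at least 1 CPM (miR-1964 added to those 4), 3 with the authors' denominators (miR-3968 added) and 15 with no filter. More precursors were compared with the lower CPM minima and without the 10 most abundant (289), but not with 1 precursor per set of copies, where the smaller totals raise the CPM of miR-2137 and miR-5121; plain totals shift every log2 fold by 0.13. The lists outside the central 95% of random lists numbered 1, and 2 without the 10 most abundant (erythrocyte added), 2 at a mean of at least 1 CPM (Dlk1-Dio3 cluster added) and 3 with no filter (both added); the cause was not tested. At a mean of at least 50 CPM the 1 such list was the erythrocyte list, which counts miR-451 in 2 precursors of equal counts, since the epithelium list kept 2 members, with a median of -0.33 and no percentile; in the other alternatives that list ranged from -0.74 to -0.49 at percentiles up to 0.41. Of 102 named precursors, 34 changed sign under some scaling or treatment of copies. None had a log2 fold over 0.13 in size, a limit that the largest shift sets. The medians of 12 of 17 lists changed sign under some alternative. No leave-one-out or paired analysis was possible because each group has 1 library. Depth limits the 432 precursors at 0 in both libraries and those with few counts; the spread between animals is unknown.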

Other observations

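The miRNAs in this part were chosen after their values were seen; the tests on neighbouring precursors were written before their result. The sensory and epithelial miR-183 cluster on chromosome 6 was lower in HC, with miR-182 at a log2 fold of -0.61 (277.5 CPM in HC, 423.6 in NC) and miR-183 at -0.68 (36.4 and 58.2 CPM). Their neighbour miR-96 had 20 counts in HC and 32 in NC, too few for a difference to be detectable. miR-192 (-0.25) and miR-194 (-0.38 and -0.35), a pair abundant in gut and liver, were lower in HC too. The miR-378 relatives miR-378b and miR-378d lay at -0.33 and -0.34, while miR-15b (0.47) and the vascular miR-100 (0.33) were higher in HC.

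At a mean below 10 CPM, miR-5121, whose hairpin overlaps the snoRNA gene Snord33 in Rpl13a, was 5.03-fold higher in HC (4.03 to 6.33, from 393 counts against 100). miR-2137, on the X chromosome in an intron of Zfp185, was 4.51-fold higher (3.64 to 5.63, from 384 against 109). Both point values exceed the 4.19-fold of miR-6236, but their counting intervals overlap its interval (3.99 to 4.40).

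Neighbouring precursors, transcribed as 1 unit in many miRNA clusters, may share their difference between the libraries. The 47 pairs of neighbours within 10 kb, of different miRNAs with 1 precursor kept per set, differed by a median of 0.17 in log2 fold, at percentile 0.63 of 10000 random re-pairings of the same 77 precursors (central 95% 0.18 to 0.34). For the pairs kept, such closeness could arise in part at the level of the cluster or of the cells that express it. Neighbours were left out where the copy kept for a set lies at another locus, so the result does not cover them. Some of these lay apart, as miR-1a-2 (0.47) and miR-133a-1 (-0.01) or let-7f-1 (-0.44) and let-7a-1 (0.02) did. Others lay close, as miR-19b-1 (-0.26) and miR-92a-1 (-0.25) or miR-30c-1 (-0.11) and miR-30e (-0.10) did. Neighbours of like sequence can also share reads or biases, which was not tested. Among the kept pairs of the Dlk1-Dio3 cluster, too, some neighbours lay far apart, as miR-300 (-0.09) and miR-376b (0.80) did.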
